A study of Mus musculus with 10 samples.

How the data were processed

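The analysis used 12 processed tables from the mouse embryonic fibroblast series, which covers 10 samples. Each of the 6 RNA samples came with a table from run 55 and a table from run 56. The 4 chromatin immunoprecipitation samples were not analysed here. Per the file headers, each deposited table gives a gene symbol, a length in kilobases (len_kb) and RPKM, which is reads scaled by transcript length and by the number of mapped reads, and the authors' values were used without rescaling. The submitters' processing notes name the mm9 genome build. The aligner, the counting program and the gene annotation are not given in the sources used here. A reference table on a later mouse build was used for gene names only, and 22284 of the 33108 gene symbols had a match in it.

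Between 60 and 119 entries per file carried region names in place of gene names, held at most 0.215% of the summed signal, and were left out. The 3 symbols printed more than once in a file were also left out. Read depth was estimated from the step size of RPKM times length among genes up to 1 kb long with under 4.5 reads, which gave between 10.4 and 18.0 M reads per file. At a length of 1 kb, 3 reads then correspond to between 0.167 and 0.289 RPKM. Floors and intervals of this kind cover counting error only.

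RPKM was transformed as log2 of RPKM plus 1. The value of a sample was the mean of its 2 runs, and the runs of a sample were counted as 1 replicate because the labels list them under the same sample. Whether both runs read the same library is not given in the sources used here, and the runs of the treated Atf4 knockout sample differed most, with a standard deviation of 0.447. Genes with a mean of at least 1 RPKM over the 6 samples were kept, which left 13547 genes. A gene was called changed between a pair of samples when it differed at least 2-fold in the same direction in run 55 and in run 56. With 1 sample per group these calls carry no p-value, and no difference between a pair of samples has a replicate check. A weaker response in a knockout was counted among the genes induced in wild-type cells, where the knockout response had to be lower by at least 1 on the log2 scale in each run. For gene lists the same difference was counted over all measured members.

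The average tunicamycin effect was fitted with limma on the 6 sample values, with a term for genotype and a term for tunicamycin, moderated variances with a trend, and Benjamini-Hochberg adjustment at 5%. Its p-values measure only how far the tunicamycin responses of the 3 genotypes differ, since each genotype has 1 treated and 1 mock sample. They hold no spread between cultures of the same genotype. Gene lists were tested in the same model with camera at a preset correlation of 0.01 for lists with at least 5 measured members. With the preset, camera compares members with the other genes and takes genes as the units. Its p-values therefore do not measure how far the genotypes agree. With an estimated correlation it uses only the 2 residual degrees of freedom of the fit, which raises p even without correlated members. Medians of lists within a pair of samples were compared with 10000 random lists matched for mean expression.

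A total of 31 gene lists were written down from general knowledge. They covered integrated stress response factors, ER chaperones and folding enzymes, ER-associated degradation and translocation, amino acid synthesis and one-carbon enzymes, amino acid transporters, cytosolic and mitochondrial aminoacyl-tRNA synthetases, translation factors, cytosolic ribosomal proteins, cholesterol synthesis and uptake, proliferation, apoptosis, p53 targets, extracellular matrix, substrates of IRE1-dependent decay, oxidative stress, autophagy, interferon-stimulated genes, Hox genes, immediate early genes, sex-linked genes and markers of fibroblasts, smooth muscle, cartilage and bone and other cell types. Of 680 entries 4 had no match in the tables, and 36 were matched through an older symbol. The sample groups, the comparisons, the thresholds, the gene lists and the alternative settings were chosen before the data were examined, except for 1 alternative setting that was added later and is named with its values. Genes named in the report are from the 10 largest changes in each direction per comparison, the targeted genes, and list members with the largest changes. Identifiers of clones, loci and predicted genes were passed over.

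In simulations of the mock wild-type sample, with planted changes and the spread between runs as the only noise, the 2-run rule found 93 of 100 genes changed 4-fold and 75 of 100 changed 3-fold, with 0 false calls. These simulations hold no difference between cultures, so they say nothing on false calls from that source. In 20 simulations the limma model found on average 99.8 of 100 genes planted at 2 on the log2 scale. It made on average 20.1 false calls, which were 9.14% of its calls and so above the 5% set. The planted change was the same in each genotype. These simulations therefore do not show how many genes are found when the response differs between genotypes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.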

Results

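The series measured RNA of mouse embryonic fibroblasts of 3 genotypes, wild type, Chop knockout and Atf4 knockout, with mock treatment or with tunicamycin. Tunicamycin blocks N-glycosylation and causes stress in the endoplasmic reticulum (ER). ATF4 and CHOP are transcription factors made during that stress, and CHOP is encoded by Ddit3. The cells came from C57BL/6 embryos of 11.5 to 12.5 days. The treatment protocol gives 10 h of tunicamycin and the series design gives 8 h. There was n = 1 sample per group, sequenced in 2 runs, so each genotype is also 1 cell line. A change below is on the log2 scale, with levels in RPKM, and "rose" or "fell" is used where both runs passed a 2-fold difference.

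Atf4 transcript rose in wild-type cells from 80.1 to 330.2 RPKM with tunicamycin, a change of 2.03, and in Chop knockout cells from 93.5 to 353 RPKM, a change of 1.91. In Atf4 knockout cells it was at 33.6 RPKM with mock treatment and 30.2 RPKM with tunicamycin. The runs disagreed in direction there, with a change from 42.9 to 51.1 RPKM in run 55 and from 24.2 to 9.21 RPKM in run 56. Ddit3 rose from 19.4 to 734 RPKM in wild-type cells, a change of 5.17. It rose less in Chop knockout cells, from 14.5 to 59.3 RPKM, and in Atf4 knockout cells, from 9.28 to 109.7 RPKM. With tunicamycin, Atf4 in its knockout was at -3.41 against wild type, with -2.71 in run 55 and -4.98 in run 56. Ddit3 in its knockout was at -3.61. With mock treatment Atf4 was at -1.23, short of 2-fold in run 55 at -0.93, and Ddit3 was at -0.40. The levels left in the knockouts count transcript, and transcript from outside a deleted part can persist. The plot of the targeted genes shows the levels in each run.

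**Figure D1:**
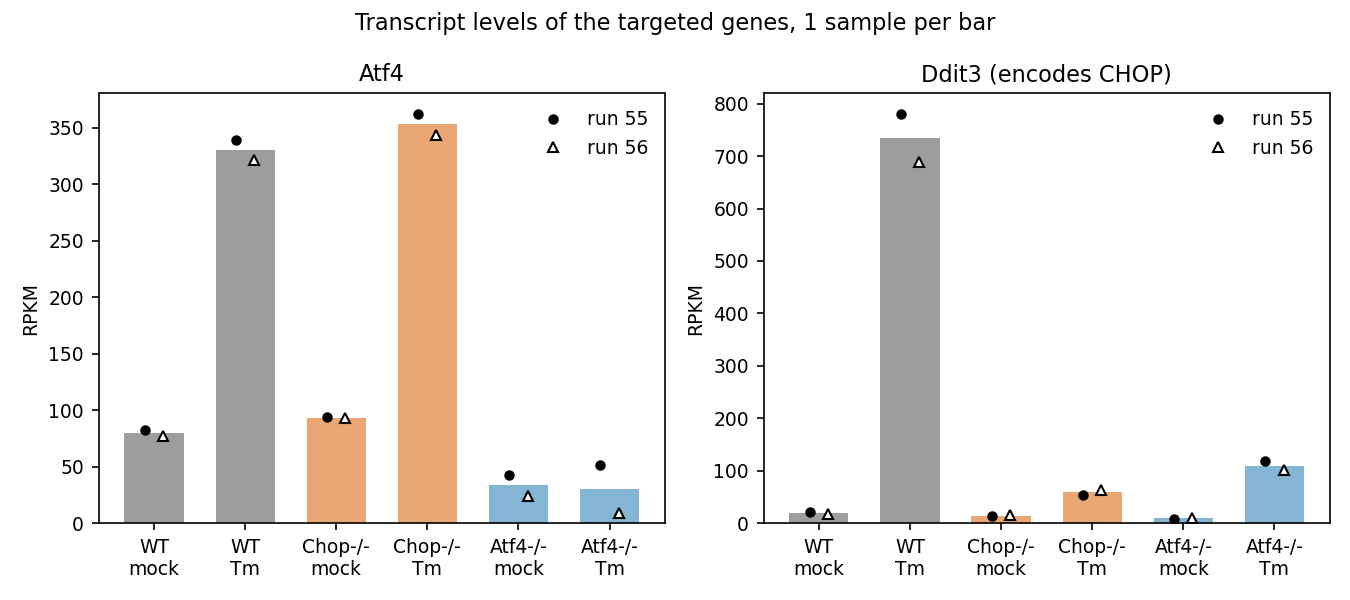
RPKM of Atf4 and Ddit3 in each of the 6 samples, with bars for the mean and points for run 55 and run 56. Ddit3 reached 734 RPKM in wild-type cells with tunicamycin and 59.3 RPKM in Chop knockout cells.

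The runs of a sample differed least for wild-type cells with tunicamycin, with a standard deviation of 0.244 between runs, and most for Atf4 knockout cells with tunicamycin, with 0.447. In that last sample 449 genes differed at least 2-fold between its runs, against 32 in the treated wild-type sample. The correlation of fold changes between run 55 and run 56 was 0.934 for the wild-type response, 0.894 for the Chop knockout response and 0.492 for the Atf4 knockout response. It was 0.509 for the difference between the Atf4 knockout and wild-type responses and 0.741 for the Chop knockout. Per-gene differences between the runs correlated at 0.797 between the treated Atf4 knockout and mock wild-type samples and at 0.761 with treated wild-type cells. The mock Atf4 knockout sample was at -0.046 and -0.004 with the wild-type samples and 0.069 with the treated Atf4 knockout sample, but at 0.538 and 0.372 with the mock and treated Chop knockout samples.

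In wild-type cells Trib3, Ddit3 and Herpud1 had the largest increases with tunicamycin. Trib3, a pseudokinase induced by ER stress, rose by 5.48, from 2.24 to 144 RPKM. Herpud1, which acts in ER-associated degradation, rose by 5.01 to 405 RPKM, and the ER proteins Creld2 and Sdf2l1 rose by 4.84 and 4.71. In all, 474 genes rose and 499 fell with n = 1 sample per group, or 394 and 605 with each file scaled to a common median. The glycine transporter Slc6a9 rose by 4.83, Cdsn, a protein of skin cell junctions, by 4.26, the secreted factor Angptl6 by 4.14, and Chac1, which degrades glutathione, by 3.99 to 76.1 RPKM. Car6 was listed at 0 RPKM in mock cells and at 19.7 RPKM with tunicamycin. Among the largest decreases, haptoglobin (Hp) fell by 4.49 on the log2 scale, from 213 to 8.54 RPKM, and the surface proteins Tm4sf1 and Ly6a by 4.10 and 3.97. The collagenase Mmp13 fell by 3.93 on the log2 scale, Angptl7 by 3.87, lumican (Lum) by 3.77, Serpina3n by 3.75 and Serpina3f by 3.57. Ctgf fell from 81.0 to 5.78 RPKM, and Mgp, an inhibitor of calcification, from 1696 to 139.5 RPKM.

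Among the gene lists in wild-type cells, ER chaperones and folding enzymes had a median of 1.88, with 17 of 24 members raised, and all 24 were higher in both runs. ER-associated degradation had a median of 0.80, with 13 of 29 raised. Integrated stress response factors had a median of 1.81, with 15 of 21 raised, amino acid synthesis and one-carbon enzymes a median of 2.0, with 15 of 21 raised, and cytosolic aminoacyl-tRNA synthetases a median of 1.77, with 12 of 20 raised. In these lists Atf5 rose from 30.3 to 262 RPKM, the mitochondrial folate enzymes Aldh1l2 and Mthfd2 rose by 3.65 and 2.77, the serine enzyme Psph by 2.63, asparagine synthetase (Asns) by 2.55, and the tryptophan, alanine and asparagine synthetases Wars, Aars and Nars by 3.06, 2.18 and 2.13. Of 18 amino acid transporters 7 rose, among them Slc7a5 by 3.60 and Slc3a2 by 3.41, which together form a leucine carrier. Cholesterol synthesis and uptake had the lowest median, -1.72, with 17 of 23 members lowered, among them Acat2 by 3.10 and Idi1 by 3.06. Extracellular matrix genes had a median of -0.69, with 14 of 35 lowered and 2 raised, Serpinh1 by 1.22 and Timp3 by 1.15. Thbs1 fell by 2.37 and Lox by 2.11 on the log2 scale. Regulated substrates of IRE1-dependent decay had a median of -0.91, and 3 of 8 fell, with Scara3 at -2.19.

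In Chop knockout cells Cth, Creld2 and Chac1 had the largest increases with tunicamycin. Cth, an enzyme of cysteine synthesis, rose by 4.70, from 2.32 to 85.1 RPKM, Creld2 by 4.42, and Chac1 by 4.32 to 86.5 RPKM. The chaperone Hspa5 rose by 3.61 to 2999 RPKM. With n = 1 sample per group 255 genes rose and 358 fell. Sdf2l1 and Herpud1 rose by 4.09 and 4.04, the transporters Slc6a9 and Slc7a3 by 3.74 and 3.71, Aldh1l2 by 3.66, and the secreted peptide Adm2 by 3.55. Ly6a fell from 67.5 to 5.79 RPKM, the peptide Vip from 25.5 to 1.91 RPKM, hyaluronan synthase Has2 from 36.7 to 3.34 RPKM, and the cytokine Il6 from 9.64 to 0.435 RPKM. Acat2 fell by 2.83 on the log2 scale, thymidine kinase Tk1 by 2.82, Tnfrsf11b by 2.79, Ly6c by 2.52, Serpina3g by 2.47 and the chemokine Cx3cl1 by 2.40.

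Lists of folding, stress and amino acid genes were raised in Chop knockout cells. Medians were 1.95 for ER chaperones, with 17 of 24 raised, 0.91 for ER-associated degradation, with 12 of 29 raised, and 1.86 for integrated stress response factors, with 16 of 21 raised. Amino acid synthesis had a median of 1.70, with 16 of 21 raised, and cytosolic aminoacyl-tRNA synthetases 1.15, with 11 of 20 raised. Of 18 amino acid transporters 10 rose, among them Slc7a5 by 3.02, and 2 fell, Slc7a2 by 1.06 and Slc1a3 by 1.37 on the log2 scale. Proliferation genes had a median of -1.07, with 17 of 34 lowered, against -0.28 and 2 of 34 in wild-type cells. Among them Mki67 was at -1.60 in the knockout and at -0.56 in wild-type cells. Cholesterol genes had a median of -1.46, with 18 of 23 lowered, and matrix genes a median of -0.68, with 9 of 35 lowered.

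In Atf4 knockout cells ER folding genes rose with tunicamycin. Herpud1 rose by 3.95, from 6.73 to 118 RPKM, Sdf2l1 by 3.94, from 18.2 to 294 RPKM, and Creld2 by 3.56, from 42.9 to 518 RPKM. With n = 1 sample per group 104 genes rose and 126 fell in both runs. Ddit3 rose by 3.43, the co-chaperone Dnajb9 by 3.18, the secreted ER factor Armet by 3.12, the oxidase Ero1lb by 3.03, Hspa5 by 2.92 to 2188 RPKM, the thioredoxin inhibitor Txnip by 2.68 and the chaperone Hyou1 by 2.66. The chemokine genes Cxcl1, Ccl2 and Cxcl5 fell by 3.63, 3.26 and 2.52 on the log2 scale, with Cxcl1 at 30.6 RPKM in mock cells and 1.56 RPKM with tunicamycin. Genes of sterol supply fell as well, with Fdps at -2.40, Idi1 at -2.19 and Sc4mol at -2.17. The calcium-binding protein S100a4 fell from 169 to 20.9 RPKM, and Idh1 fell from 29.4 to 5.64 RPKM. Run 55 alone gave 416 changed genes for this response and run 56 alone gave 817.

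The ER chaperone list had a median of 1.81 in Atf4 knockout cells, with 18 of 24 raised, and ER-associated degradation a median of 0.82, with 9 of 29 raised. By contrast 0 of 21 amino acid synthesis genes, 0 of 21 integrated stress response factors and 0 of 20 cytosolic aminoacyl-tRNA synthetases rose, with medians of -0.31, -0.08 and 0.13. Ddit3, which did rise, was not a member of the stress factor list. Asns was at 0.27, Mthfd2 at -0.40, Psph at -0.46, and Slc7a5 at 30.5 RPKM with mock treatment and 28.2 RPKM with tunicamycin. Of the stress factors 3 fell, Cdkn1a by 2.01, Ddit4 by 1.83 and Ndrg1 by 1.35 on the log2 scale. Slc3a2, at 1.58, was the 1 amino acid transporter of 18 that rose. Cholesterol genes had a median of -1.35, with 17 of 23 lowered, and 4 of 35 matrix genes fell. The plot of list medians shows these lists side by side, and the plot of single members shows the genes within a set of 3 lists.

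**Figure D2:**
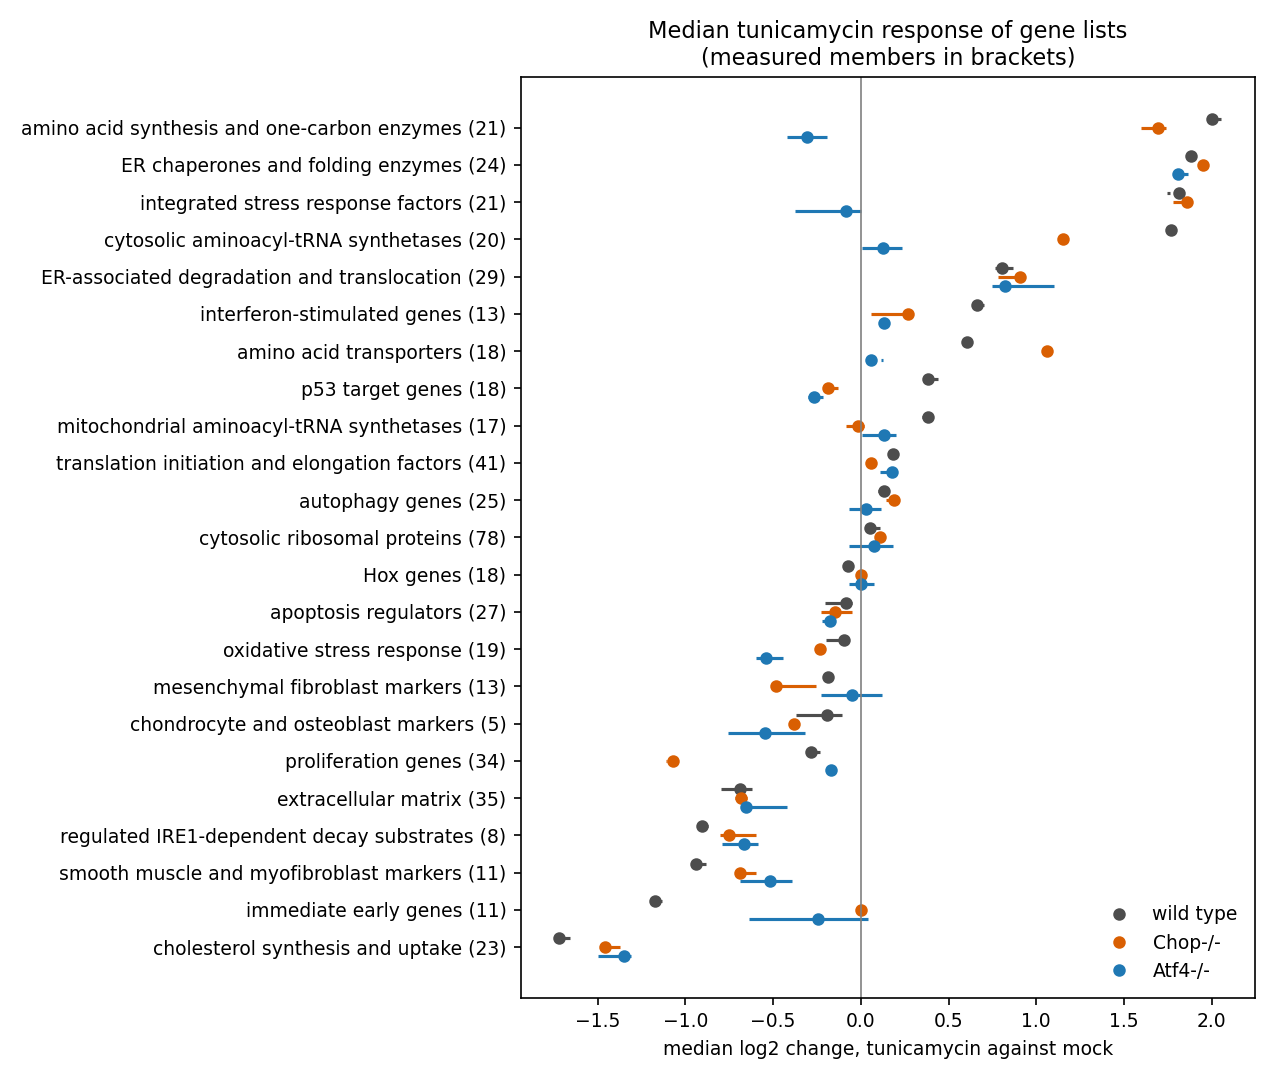
Median log2 change with tunicamycin for each gene list, coloured by genotype, with lines joining the values of run 55 and run 56 and the number of measured members in brackets. Amino acid synthesis had a median of 2.0 in wild-type cells and -0.31 in Atf4 knockout cells, and the ribosomal protein list in Atf4 knockout cells changes direction to -0.07 with run 56 alone.

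**Figure D3:**
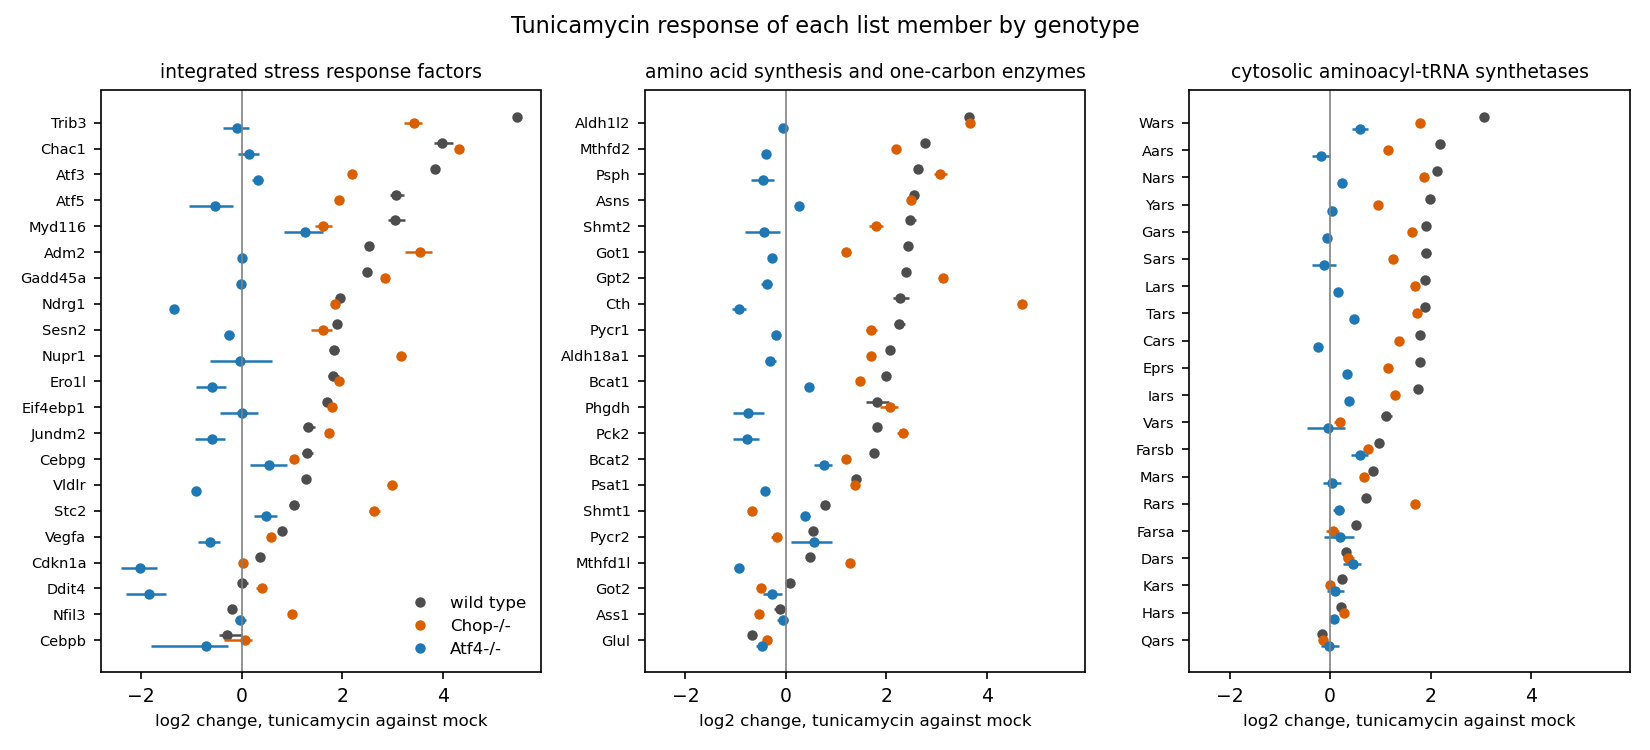
Log2 change with tunicamycin of each member of a set of 3 lists, coloured by genotype, with lines joining the values of the 2 runs. Trib3 was at 5.48 in wild-type cells, and at -0.08 in Atf4 knockout cells.

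Many stress factors and amino acid enzymes responded less to tunicamycin in Atf4 knockout cells than in wild-type cells. Among the 474 genes that rose in wild-type cells, 193 had a response lower by at least 1 in Atf4 knockout cells in each run, and 1 had a larger response, Txnip by 1.49. The 193 of 474 became 114 of 261 with a pseudocount of 5 and 352 of 619 with run 56 only. Trib3 had the largest difference, -5.56, followed by Cdsn at -5.42, Slc6a9 at -4.91, Angptl6 at -4.39, Chac1 at -3.85, Aldh1l2 at -3.72, Slc7a5 at -3.71, Atf5 at -3.60 and the transcription factor Atf3 at -3.53. Trib3, Angptl6, Chac1 and Aldh1l2 were under 1 RPKM in both Atf4 knockout samples. With 1 added to RPKM, their differences mostly give the size of the wild-type response. Car6 reached 19.7 RPKM in treated wild-type cells only. Over all measured members of a list, whether or not they rose in wild-type cells, the medians of the difference were -2.38 for amino acid synthesis, where 15 of 21 members responded less, -2.13 for integrated stress response factors, where 17 of 21 did, and -1.39 for aminoacyl-tRNA synthetases, where 11 of 20 did. Cth, Mthfd2 and Psph were at -3.20, -3.17 and -3.09, and the cystine transporter Slc7a11 was at -2.81. ER chaperones had a median difference of -0.18, with Hyou1 at -1.24 and Hspa5 at -1.06 the 2 of 24 members that responded less. ER-associated degradation had a median difference of -0.12, and 0 of 29 members responded less. Ddit3 itself was at -1.74.

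In Chop knockout cells 107 of the 474 genes responded less and 5 responded more, with an all-gene median of -0.14 for the difference. The 107 of 474 became 47 of 261 with a pseudocount of 5, 65 of 382 with a mean of at least 5 RPKM and 202 of 619 with run 56 only. Cdsn was at -4.46, Angptl6 at -4.09, the protease inhibitor Timp3 at -3.27, Ddit3 at -3.21, the acyl-CoA thioesterase Acot2 at -3.17, Spry1 at -2.84, Nrip2 at -2.76 and the helicase Recql4 at -2.75. Cdsn, Angptl6 and Nrip2 were under 1 RPKM in both Chop knockout samples. With 1 added to RPKM, the differences of these genes mostly give the size of the wild-type response. Arhgap20 rose from 0.48 to 8.40 RPKM in wild-type cells and was near 0 in the knockout, and Car6 again reached 19.7 RPKM in treated wild-type cells only. Larger responses were seen for Cth, by 2.42, Vldlr, by 1.73, Dhrs9, by 1.42, Nupr1, by 1.34, and Phf10, by 1.01. Integrated stress response factors had a median difference of 0.12, a direction that changes to -0.01 with run 56 alone, and members went both ways. Of 21 members 4 responded more, with Vldlr, Stc2 and Nupr1 at 1.73, 1.60 and 1.34, and 3 responded less, with Trib3, Atf3 and Myd116 at -2.05, -1.66 and -1.43. Proliferation genes had a median difference of -0.80, which is -0.66 relative to all genes, and Mcm7 and Aurkb were at -1.58 and -1.29. The medians of ER chaperones and ER-associated degradation, -0.09 and -0.11, turn to 0.05 and 0.04 when each file is scaled to a common median.

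A total of 81 genes responded less in both knockouts, where 43.6 would be expected if the sets were independent. Both sets were counted against the same wild-type samples, and part of the excess may come from them. Simulated knockouts with the spread between runs as their only noise shared 0.02 genes on average, which leaves out any difference between the lines. The excess over either value is therefore not evidence of a shared effect of the knockouts. Responses were lower in the Atf4 knockout alone for 112 genes, in the Chop knockout alone for 26, and in neither for 255. Of the genes raised in wild-type cells 180 also rose in Chop knockout cells and 81 in Atf4 knockout cells.

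With tunicamycin, the largest differences between Atf4 knockout and wild-type cells included Lcn2 and Saa3. Lcn2 was at 1027 RPKM in wild-type cells and listed at 0 in the knockout, and the acute-phase gene Saa3 was at 941 against 0.59 RPKM. Lower values were also found for complement C3, at -8.00 against wild type, the chemokine Cxcl1, at -7.46, and decorin (Dcn), at -7.45. In total 1231 genes were higher and 1419 lower with n = 1 sample per group, and the all-gene median was 0.10. With each file scaled to a common median 1008 were higher and 1581 lower. H19, a noncoding RNA, was at -7.31, Igfbp2 at -7.29, ceruloplasmin (Cp) at -7.11 and Aldh1l2 at -6.97, and Ppbp was at 127 RPKM in wild-type cells and listed at 0 in the knockout. The amino acid transporter Slc38a4 was higher by 5.45, periostin (Postn) by 4.19, the cell-cycle factor Mybl2 by 4.14, Cd34 by 3.95, Lrrc8d by 3.84, Id2 by 3.71 and Cyr61 by 3.65. Tspan6 and Cart1 were listed at 0 in wild-type cells and were at 12.8 and 12.1 RPKM in the knockout. The remaining gene among the 10 most raised is a member of the sex-linked list and is counted with it below.

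Of 21 integrated stress response factors 19 were lower in treated Atf4 knockout cells, with a median of -3.40 and with Trib3, Nupr1 and Gadd45a at -6.39, -6.07 and -6.02. Amino acid synthesis had a median of -1.45, with 14 of 21 lower, Pck2 at -4.15 and Cth at -3.74, and aminoacyl-tRNA synthetases a median of -0.79, with 8 of 20 lower and 2 higher. The p53 targets had a median of -1.27, with 10 of 18 lower and Fas at -4.16. Proliferation genes had a median of 1.94, with 32 of 34 higher, among them Rrm2 by 3.22, Cdc6 by 3.13 and Mcm5 by 3.08, and cyclin D1 (Ccnd1) was lower at -1.53. ER chaperones had a median of -0.40, with 5 of 24 lower, led by Dnajb9 at -2.45.

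With tunicamycin, Chop knockout cells had higher Col4a1, Col4a2 and Cd34 and lower Cxcl1 and Saa3 than wild-type cells. The collagen IV chains Col4a1 and Col4a2 were higher by 4.63 and 4.29, Cd34 by 5.13, from 0.35 to 46.2 RPKM, Serpinb2 by 4.88 and the natriuretic peptide receptor Npr3 by 4.87. In total 466 genes were higher and 768 lower with n = 1 sample per group, and the all-gene median was -0.11. With each file scaled to a common median 549 were higher and 695 lower. Cd59a was higher by 4.22, Evi2a by 4.18, Rbm19 by 4.12 and endoglin (Eng) by 4.05, and Dgkk was listed at 0 in wild-type cells and at 20.8 RPKM in the knockout. Cxcl1 was at 448 RPKM in wild-type cells and 0.035 RPKM in the knockout, and H19 at 268 RPKM and listed at 0. Also lower were Cdsn at -6.81, Saa3 at -5.77, clusterin (Clu) at -5.53, Wisp2 and Lcn2 at -5.09 each, Rasl11a and Renbp at -4.82 each, and Cyp7b1 at -4.74. Integrated stress response factors had a median of -0.79, with 8 of 21 lower, among them Myd116 at -2.61, Cebpb at -1.80 and Atf5 at -1.58, and Ddit4 was higher by 1.48. ER chaperones had a median of -0.13, and 0 of 24 differed. Amino acid synthesis and aminoacyl-tRNA synthetases had medians of 0.48 and 0.21, each with 1 member higher, Ass1 by 1.38 and Rars by 1.81.

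In mock-treated Atf4 knockout cells Lcn2, Saa3, Dcn and Mgp were among the genes furthest below their wild-type level. Lcn2 was at 2729 RPKM in wild-type cells and 0.035 RPKM in the knockout. Saa3 was at -10.81 against wild type, 0.82 RPKM in place of 3274, Dcn at -8.92, Mgp at -8.69, 3.12 RPKM in place of 1696, and the iron reductase Steap4 at -8.39. In total 1473 genes were higher and 1253 lower with n = 1 sample per group, with an all-gene median of 0.20. When each file is scaled to a common median the split becomes 1042 higher and 1526 lower, which moves the share of higher genes from 54.0% to 40.6%. Cp was at -8.27, C3 at -8.15 and the Wnt inhibitor Sfrp1 at -8.13. The chemokine Ppbp was at 294 RPKM in wild-type cells and 0.055 RPKM in the knockout. Serpina3n was at 241 RPKM in wild-type cells and 0.045 RPKM in the knockout. Slc38a4 was higher by 5.14, the actin-binding protein Cotl1 by 4.49, Postn by 4.33, Pcolce2 by 3.98 and Stmn2 by 3.80. Lrrc8d was at 0.055 RPKM in wild-type cells and 15.9 RPKM in the knockout. Six2 and Tspan6 were listed at 0 in wild-type cells and at 15.8 and 12.1 RPKM in the knockout.

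Relative to all genes, proliferation genes were higher in mock Atf4 knockout cells with a median of 1.68, and 31 of 34 were higher, among them Rrm2 by 2.80, Mcm2 by 2.59 and Mcm5 by 2.57, while Ccnd1 was lower at -3.01. Integrated stress response factors were at -1.36 relative to all genes, with 10 of 21 lower, Nupr1 at -4.19 and Gadd45a at -3.51. Matrix genes were at -1.29 relative to all genes, with 17 of 35 lower and 3 higher, and fibroblast markers at -1.92, with 8 of 13 lower and Pdgfra at 4.54 RPKM against 108 RPKM in wild-type cells. Amino acid synthesis was at 0.13 relative to all genes, with Shmt1 and Mthfd2 higher by 2.19 and 1.71 and Aldh1l2 lower at -3.25. Of 2726 genes that differed with mock treatment, 956 were higher and 937 lower with tunicamycin as well.

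Mock-treated Chop knockout cells had lower H19, Cxcl1 and Saa3 and higher Col4a1 and Col4a2 than mock wild-type cells. H19 was at 892 RPKM in wild-type cells and 0.01 RPKM in the knockout, and Cxcl1, Saa3 and Clu were lower at -8.90, -7.41 and -7.05. Col4a1 and Col4a2 were higher by 4.40 and 4.36, and the RNA-binding protein Rbm19 by 4.74, from 5.73 to 179 RPKM. In total 478 genes were higher and 680 lower with n = 1 sample per group. Npr3 was higher by 4.36, the chloride channel Tmem16a by 4.33, and Nptx1 and Cd34 by 4.24 each. Dgkk and Prokr2 were listed at 0 in wild-type cells and at 35.2 and 26.8 RPKM in the knockout. Also lower were Wisp2 at -6.08, Lcn2 at -5.55, thrombomodulin (Thbd) at -5.50, Rasl11a at -5.35, Cdo1 at -5.10 and Plac8 at -5.06. The p53 targets had a median of 0.81, with 7 of 18 higher, led by Perp at 3.30 and Mdm2 at 1.96, and 2 lower. Proliferation genes had a median of 0.61, with 5 of 34 higher, and integrated stress response factors a median of -0.45, with 7 of 21 lower and Stc2 at -2.62. Genes that differed in the same direction with tunicamycin as well numbered 291 higher and 464 lower.

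Across the 3 genotypes ER folding genes rose and sterol genes fell with tunicamycin. In the limma model with Benjamini-Hochberg adjustment, Herpud1 rose by 4.33 on average (standard error 0.230, adjusted p = 0.00351), Creld2 by 4.28 (adjusted p = 0.00409) and Sdf2l1 by 4.25 (adjusted p = 0.00290), each in 3 of 3 genotypes. A total of 595 genes passed, 267 up and 328 down, and 3707 before adjustment, on 3 treated against 3 mock samples. The count depended on the setting, with 27 genes without the Chop knockout, 267 without wild type, 365 without the Atf4 knockout and 1 with no filter on low values. By limma with that adjustment, Hspa5 rose by 3.50 (adjusted p = 0.00409), Armet by 3.34 (adjusted p = 0.00290), Hyou1 by 3.30 (adjusted p = 0.00726), Dnajb9 by 3.30 (adjusted p = 0.00290), Pdia4 by 3.05 (adjusted p = 0.00351) and Ero1lb by 2.89 (adjusted p = 0.00290). Ddit3 rose by 3.52 with a wider standard error of 0.566 (adjusted p = 0.0372 by limma, Benjamini-Hochberg), a call that was lost with a pseudocount of 5 (adjusted p = 0.0628), without the Chop knockout (adjusted p = 0.0689) and without the Atf4 knockout (adjusted p = 0.0773). The largest decreases were S100a4 at -2.75 (limma, Benjamini-Hochberg adjusted p = 0.00366), Acat2 at -2.58 (adjusted p = 0.0145) and Idi1 at -2.52 (adjusted p = 0.00815). Has2 fell by 2.46 on the log2 scale, Mgp by 2.30, Ccl2 by 2.24, Fdps by 2.13 and Dbi, which binds acyl-CoA, by 2.01. Each of these genes had the same direction in 3 of 3 genotypes, but Hyou1, Acat2, Idi1, Has2, Mgp, Ccl2 and Dbi were not called by limma without the Chop knockout.

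By limma with Benjamini-Hochberg adjustment over all genes, 21 of 24 ER chaperones and 17 of 29 ER-associated degradation genes passed as higher with tunicamycin. When adjusted over the list alone, 24 of each list did. These counts set no minimum size of change. Camera called the lists up with adjusted p = 8.58e-27 and 1.07e-19, and gave adjusted p = 0.145 and 0.133 with an estimated correlation. Of 23 cholesterol genes 20 fell (21 adjusted over the list alone), and camera called the list down with adjusted p = 9.83e-19, or adjusted p = 0.133 with an estimated correlation. Matrix genes had 11 of 35 lowered and 1 raised, 23 lowered and 1 raised when adjusted over the list alone, with camera adjusted p = 5.92e-12, or 0.133 with an estimated correlation. Smooth muscle markers had 5 of 11 lowered (9 over the list alone), with camera adjusted p = 6.55e-07, or 0.187 with an estimated correlation. Substrates of IRE1-dependent decay had 3 of 8 lowered (5 over the list alone), with camera adjusted p = 0.00039, or 0.236 with an estimated correlation. In total camera called 16 of 24 lists, 9 up and 7 down, and 0 lists with an estimated correlation, where 5 lists had an unadjusted p under the same threshold. The estimated correlation was -0.012 for ER-associated degradation, -0.010 for matrix genes and -0.143 for IRE1-dependent decay. These are below the preset, so correlated members do not account for the lost calls of these lists. It was 0.120 for ER chaperones, 0.032 for cholesterol genes and 0.025 for smooth muscle markers.

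Several further lists had few members that passed limma for the average effect. The fit counts a response that differs between genotypes as spread, so few calls do not mean a small response in each genotype. Integrated stress response factors had 2 of 21 raised, also 2 over the list alone, with camera adjusted p = 0.000176, or 0.481 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases had 1 of 20 raised (8 over the list alone), with camera adjusted p = 9.77e-07, or 0.394 with an estimated correlation. Amino acid synthesis had 1 of 21 raised (2 raised and 1 lowered over the list alone), with camera adjusted p = 0.000939, or 0.462 with an estimated correlation. Proliferation genes had 1 of 34 lowered, with camera adjusted p = 6.55e-07, or 0.472 with an estimated correlation. Translation factors were called up with 3 of 41 raised (7 over the list alone) and camera adjusted p = 0.00197, or 0.394 with an estimated correlation. Mitochondrial aminoacyl-tRNA synthetases had 0 of 17 raised by limma over all genes (2 over the list alone and 4 before adjustment), with camera adjusted p = 0.0395, or 0.518 with an estimated correlation, and that call was lost with run 56 only (adjusted p = 0.0952). Amino acid transporters had 1 of 18 raised (3 raised and 1 lowered over the list alone) and were not called, with camera adjusted p = 0.0567, but were called in several alternative settings, for example with common scaling (adjusted p = 0.0451).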

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

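The items in this part were picked out by rules set down in advance, and 0 tests were chosen after results were seen.

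A total of 5 genes rose in a genotype and fell in another with tunicamycin, and the difference between genotypes was not tested for any of them. Cdsn was at 4.26 in wild-type cells, -0.20 in Chop knockout cells and -1.15 in Atf4 knockout cells. Timp3, an inhibitor of matrix proteases, was at 1.15, -2.12 and -2.14 in the same order. Ndrg1, a stress-responsive gene, was at 1.95, 1.86 and -1.35. The remaining genes were D4Bwg0951e, at 1.35, -1.75 and -0.26, and Wisp1, at 1.26, -0.10 and -1.31.

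A search for a sample apart from its replicates was not applicable, since there was 1 sample per group. Values assigned to regions without a gene name were picked out because no comparison used them, and they held at most 0.215% of the signal of a file.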

How the results depend on the processing

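The alternatives in this part were fixed in advance except for the use of run 55 alone for the treated Atf4 knockout sample, which was chosen after results were seen. With a pseudocount of 0.1 the Chop knockout response counted 930 genes and the Atf4 knockout response 363. With a pseudocount of 5 the wild-type response counted 536 genes, the Chop knockout response 305 (171 up and 134 down), the Atf4 knockout response 129 (73 up and 56 down), weaker responses 114 in the Atf4 knockout, 47 in the Chop knockout and 41 in both, the difference to wild type with tunicamycin 1361 in the Atf4 knockout and 599 in the Chop knockout, the difference with mock treatment 1544 and 587, and the limma average 347. With a mean of at least 5 RPKM, weaker responses numbered 65 in the Chop knockout and 44 in both, and the Chop knockout differed from wild type by 792 genes with tunicamycin and 718 with mock treatment. With run 55 only the Atf4 knockout response counted 416 genes, and with the mean of the 2 runs only it counted 378. With run 56 only it counted 817 genes (237 up and 580 down), and weaker responses numbered 352 in the Atf4 knockout, 202 in the Chop knockout and 176 in both. With run 56 only 15 list medians changed sign, 3 of them outside the range of random lists before, to -0.007 for integrated stress response factors in the difference between Chop knockout and wild-type responses, -0.069 for ribosomal proteins in the Atf4 knockout response, and -0.032 for matrix genes in the difference between Atf4 knockout and wild-type responses. The limma average counted 1 gene with no filter on low values and 6 genes with no genotype term. Leaving out each genotype in turn gave 27 to 365 genes, with 27 without the Chop knockout, 267 without wild type and 365 without the Atf4 knockout. Among the named genes, Has2 and Mgp lost their limma call with a pseudocount of 5 (Benjamini-Hochberg adjusted p = 0.0829 and 0.116), Mgp with run 55 only (0.0514) and without the Atf4 knockout (0.0510), Has2 without wild type (0.0928), and Hyou1, Acat2, Idi1, Has2, Mgp, Ccl2 and Dbi lost it without the Chop knockout (adjusted p = 0.0677, 0.101, 0.0642, 0.189, 0.154, 0.144 and 0.121). Without the filter each of the named genes lost it, and without the genotype term most did. Autophagy genes lost their camera call with run 56 only (adjusted p = 0.0607), a mean of at least 5 RPKM (0.0967) and without the Chop knockout (0.148). Mitochondrial aminoacyl-tRNA synthetases lost theirs with run 56 only (0.0952), a mean of at least 5 RPKM (0.0974) and without wild type (0.152), interferon-stimulated genes with a mean of at least 5 RPKM (0.110) and chondrocyte and osteoblast markers with no genotype term (0.236). Amino acid transporters gained a call with run 55 only (0.0247), run 56 only (0.0210), no genotype term (0.00402), without wild type (0.0161) and without the Atf4 knockout (0.000706). Immediate early genes gained a call with no filter (0.0102), no genotype term (0.00402), run 56 only (0.0210) and without the Chop knockout (0.00185), and ribosomal proteins with run 55 only (0.00920) and without wild type (0.0161). Camera with an estimated correlation called 0 lists and fry called 6. With each file scaled to a common median the responses counted 999 (394 up and 605 down), 626 and 220 genes in wild-type, Chop knockout and Atf4 knockout cells, and the limma average 748. With run 55 alone for the treated Atf4 knockout sample its response counted 285 genes, weaker responses 212, and the limma average 472. Weaker responses were counted among genes that rose in wild-type cells, and that number changed with the setting as well. It was 474 in the main setting, 261 with a pseudocount of 5, 382 with a mean of at least 5 RPKM and 619 with run 56 only. The cause was not tested for any of these shifts. The genotype term already pairs each treated sample with the mock sample of its line. Of the fixed alternatives 0 were not run.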

Other observations

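In this part the tests of tunicamycin exposure, of starting expression, of loss of ATF4 and of lines from different embryos were chosen after results were seen, and the remaining tests before.

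Of 11 immediate early genes 6 fell and 2 rose in wild-type cells with tunicamycin, with a median of -1.18. Jun went from 60.2 to 7.62 RPKM in wild-type cells and stayed at 43.3 RPKM in Chop knockout cells, while Klf4 rose by 1.96 and 1.60. In Atf4 knockout cells 3 immediate early genes fell, Ier3 by 1.99, Egr1 by 1.93 and Junb by 1.48 on the log2 scale. Over the 3 genotypes camera did not call the list (adjusted p = 0.0631), although it did with run 56 only (adjusted p = 0.0210). Among 18 p53 targets 3 rose and 1 fell in wild-type cells, with Bbc3, a cell-death gene, at 1.49 and Plk2 at 1.43. In Chop knockout cells Rrm2b rose by 1.07, in Atf4 knockout cells 2 targets fell, and camera did not call the list (adjusted p = 0.808). Of 27 apoptosis regulators Bbc3 rose in wild-type cells and Casp12 fell there and in Chop knockout cells, at -1.43 and -1.56, and camera did not call the list (adjusted p = 0.107). Heme oxygenase Hmox1 rose by 1.89 in wild-type cells, from 48.0 to 181 RPKM, and by 1.46 in Chop knockout cells, and was at -0.54 in Atf4 knockout cells. The oxidative stress list as a whole was called down by camera (adjusted p = 0.000628, or 0.350 with an estimated correlation), with 3 of 19 members lowered by limma with Benjamini-Hochberg adjustment and 4 over the list alone. Interferon-stimulated genes were called up (adjusted p = 0.0104, or 0.462 with an estimated correlation), with 1 of 13 raised, also 1 over the list alone, and Ifi44 rose by 2.44 in wild-type cells. Autophagy genes were called up (adjusted p = 0.0332, or 0.378 with an estimated correlation), with 1 of 25 raised (4 over the list alone), and the cargo receptor Sqstm1 rose by 1.53 in wild-type cells.

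Of 78 ribosomal protein genes Rpl10a rose by 1.03 in wild-type cells and Rpl37a was at -1.78 in Atf4 knockout cells, and camera did not call the list (adjusted p = 0.160). The chondrocyte and osteoblast list was called down by camera (adjusted p = 0.0104, or 0.378 with an estimated correlation), with 1 of 5 lowered (4 over the list alone), while Sox9 and Col2a1 were higher by 3.11 and 2.82 in mock Chop knockout cells. Fibroblast markers were not called (adjusted p = 0.128), although S100a4 fell by 2.90, 2.38 and 2.96 on the log2 scale in wild-type, Chop knockout and Atf4 knockout cells. The lines differed in Hox genes. In mock Atf4 knockout cells 11 of 18 were lower, among them Hoxd8 at -2.77 and Hoxa7 at -2.75, 4 were higher, and the median was -1.92 relative to all genes. In mock Chop knockout cells 4 were lower, with Hoxb7 at -2.11. Tunicamycin moved few of them, with Hoxb9 at 2.39 in wild-type cells, and camera did not call the list (adjusted p = 0.742). Markers of other tissues were mostly absent, with 0 of 14 epithelial and 0 of 11 erythroid and hepatocyte markers measured, 3 of 12 endothelial, 3 of 14 macrophage, 3 of 16 skeletal muscle, 4 of 14 neural and 3 of 10 adipocyte markers. Fabp4, a fatty acid carrier of fat cells, fell by 2.09 and 1.42 on the log2 scale in wild-type and Chop knockout cells, the macrophage receptor Cd14 was at -2.62, the endothelial Flt1 at -1.05 and the neural Tubb3 at 1.71 in wild-type cells, and 0 of the skeletal muscle markers changed. Of the 6 sex-linked genes measured, 6 differed at least 2-fold between the mock Atf4 knockout and wild-type lines, 1 differed between the Chop knockout and wild-type lines, 0 responded to tunicamycin, and camera did not call the list (adjusted p = 0.578).

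No member of the lists of amino acid synthesis genes, cytosolic aminoacyl-tRNA synthetases and integrated stress response factors rose in Atf4 knockout cells with tunicamycin. Ddit3, which was not on these lists, rose there by 3.43. The median response of the ER chaperone list was 0.959 of its wild-type median, and 0.978 and 0.966 in the single runs. This argues against a much weaker tunicamycin exposure of that culture as the cause. Some of the most raised ER genes rose less, Herpud1 by 3.95 against 5.01 in wild-type cells and Hspa5 by 2.92 against 3.98. Ero1lb did not, at 3.03 against 2.91. A somewhat weaker exposure therefore stays possible. Low starting expression was tested on the 39 members that rose in wild-type cells and responded less in the knockout. The difference that picked these members includes the mock level of the knockout, and a high mock level favours being picked. The values therefore cannot exclude low starting expression for a list as a whole. As measured, the 11 aminoacyl-tRNA synthetases did not start low. Their median against wild type with mock treatment was 0.51, with quartiles of 0.23 and 0.70. The 14 amino acid synthesis genes had a median of 0.19 and quartiles of -0.85 and 1.10. The 14 stress factors had a median of -0.88, with 5 of them at least 2-fold lower, and low starting expression stays open for both lists. Loss of ATF4 itself could explain the pattern, but 2726 genes differed between the mock lines, and with 1 line per genotype another difference between the lines stays possible.

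Proliferation genes were higher in mock Atf4 knockout cells. Scaling of the files does not account for it, since the median was 1.66 with each file scaled to a common median, and 1.75 and 1.63 in the single runs. The wild-type and Atf4 knockout lines differ in genotype and so come from different embryos, and 6 of 6 sex-linked genes differed between them. Sex-linked genes can differ together, so they count as a single difference between the lines and say nothing on the growth genes. A difference between embryos could explain the growth genes, but this was not tested. An effect of ATF4 loss on growth was not tested.

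Proliferation genes were lowered by tunicamycin in Chop knockout cells more than in wild-type cells. Scaling of the files does not account for it, since the difference of responses was -0.67 with each file scaled to a common median, and -0.71 and -0.67 in the single runs. Faster growth of the mock Chop knockout culture could account for part of it, since with common scaling the list sat at 0.59 with mock treatment and at -0.24 with tunicamycin, which does not decide the question. An effect of CHOP loss itself was not tested with a further line.

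Other splits of the 6 samples into treated and mock groups were too few for a share under 0.05. Of 10 splits the real split called 595 genes and the highest other split 8, and only 1 split, the real 1, reached that count. For gene lists the real split called 16 and the highest other split 13, and again only 1 split reached the real count. The counts of 8 genes and 13 lists came from splits with both samples of a genotype on the same side. Other splits with 1 sample of each genotype on each side called 0 genes and 6, 11 and 12 lists. In any other split the tunicamycin effect enters the spread of the fit and lowers the gene count. The splits therefore give no measure of how many genes would be called without an effect. For lists, the other splits still called 6 to 13 of 24, so the number of lists called hardly separates the real split. A camera call at the preset correlation is therefore not evidence by itself that the genotypes agree.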
